A study of Mus musculus with 12 samples.

How the data were processed

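Polyadenylated RNA of neonatal mouse cardiomyocytes was sequenced in 12 libraries, 3 in each of 4 groups. The groups were PBS or PE, each with a negative-control or a lincRNA-p21 GapmeR, per the labels. PE was given for 24 hours. RNA was taken with TRIzol, and libraries were made and sequenced as paired-end reads by BGI, per the labels. Per the submitters' processing notes, reads were aligned to GRCm38.p6 with STAR, handled with SAMtools and counted per gene with featureCounts. Their versions, the annotation release and the use of strand were not given in the sources used here.

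The authors deposited 1 table with the signal of 55416 genes in 12 columns, which are read counts divided by 1 size factor per library. Each column is a multiple of a single step, and dividing by it gave whole numbers for 100% of values in every library (tolerance 0.001). Median-of-ratios factors recomputed from these recovered reads differed from the steps by at most 4.6e-10. Factors ran from 0.921 to 1.11, and recovered reads in genes from 21325485 to 22139681 per library. Mitochondrial genes held 4.33% to 10.7% of reads. Pairs of replicates differed by a chi-square per degree of freedom of 2.42 to 53.5, so no library repeats another. The table has 0 columns of no sample.

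Before the data were examined, the unit was assumed to be raw counts for edgeR, with limma on log2 values as the fallback for another unit. Since the deposited values are scaled, the fallback became the test reported here, and edgeR, DESeq2 and limma-voom on the recovered reads became alternatives. Genes with a mean value of at least 1 were tested (21799), on log2 of the value plus 1. A model with 4 group means was fitted to all 12 libraries with limma 3.58.1 and a trended prior. The 5 comparisons were PE against PBS with each GapmeR, the 2 GapmeRs within PE and within PBS, and the interaction. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. The fit had 3 libraries per group, so only differences larger than the spread of these libraries could be called. Identifiers were matched without version to GENCODE release M21, which gave a symbol to 52083 genes (35 matched with their version). The other 3333 carried 0.2% of the signal.

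Gene lists, 33 in all, and the genes to be named were also fixed before the data were examined. Named in every comparison were Trp53cor1, Nppa, Nppb, Myh7, Acta1, Myh6, Rcan1, Cdkn1a, Srsf3 and Adora2a. Further named genes were the 10 highest and 10 lowest called genes with a mean log2 CPM of at least 1 and library values that did not overlap, without predicted gene models, and up to 4 called members of each list, or 2 where none was called. For the interaction, overlap was allowed. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. A call of a list means camera at the preset correlation. Fry was run on every list, but its results are given only for the interferon list and for the lists called in the interaction. Of 296 named genes, 82 overlap another tested gene, and for 12 of these the other gene is at least as high. Fosl1, Mcm7, Cxcl10, Nop56, Plppr3 and Ccne2 are among these 12, and reads of such pairs may not have been told apart.

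The test was tested on simulated data, with 200 changed genes among simulated libraries of the same spread per gene. The changed genes lay above the lowest values tested, so the shares found do not hold for the lowest genes. Noise was drawn gene by gene, so no simulated library stood apart as a whole, unlike some real ones. For the knockdown in PE it found 89% of 2-fold and 57% of 1.5-fold changes, and for PE in knockdown cells 82% and 54%. For the interaction it found 61% and 15%. In unchanged genes it made 14, 7 and 5 calls, and 0 for PE in control cells and the knockdown in PBS.

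Alternatives fixed before were another pseudocount (0.1), no filter, a filter of CPM of at least 1 in 3 libraries, edgeR 4.0.16 with median-of-ratios factors, with total counts only and without mitochondrial genes, DESeq2 1.42.0, limma-voom, only the 6 libraries compared, a replicate block, a fold change of at least 1.5 and each library left out. Where a group was left with 2 libraries, limma pooled the spread over groups. Added after the data were seen were edgeR with TMM on recovered reads, values rescaled to the same total, the GC trend removed by lowess (span 0.3) and a fit without 3 libraries far from their groups. These were PBS control replicate 2, PBS knockdown replicate 2 and PE knockdown replicate 1. Replicate numbers were not treated as pairs in the test reported here, which was fixed without covariates before the data were examined. Looked at afterwards, the residuals of libraries of the same number correlated between -0.435 and 0.409, a range that does not itself test pairing.

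Genomic spans and exons came from the GENCODE annotation, and medians of long genes used genes with a mean value of at least 50. Bootstrap errors of medians used 1000 draws of genes or list members, so they hold no spread between libraries. Words of 11 bases shared between Trp53cor1 and mature transcripts were ranked by a score. It was the mean adjusted change of their carriers, divided by the spread over genes and multiplied by the square root of the number of carriers. Introns were left out because no genome sequence was used here. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.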

Results

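The GapmeR, an antisense oligonucleotide that directs RNase H to its target, lowered lincRNA-p21 (Trp53cor1, ENSMUSG00000085912.3, GRCm38 chromosome 17, 29057430 to 29079179, minus strand), a long noncoding RNA known as a p53 target next to Cdkn1a. Its normalised read count was 64.5 ± 5.5 in PBS with the negative-control GapmeR and 15.1 ± 6.6 in PBS with the lincRNA-p21 GapmeR (mean ± SD, n = 3 per group here and throughout). With phenylephrine (PE), an alpha1-adrenergic agonist that enlarges cardiomyocytes, it was 41.6 ± 12.5 and 9.16 ± 0.728. The lincRNA was 76.6% lower with its GapmeR in PBS and 78.0% lower in PE. Its log2 change was -2.10 ± 0.30 and -2.03 ± 0.30 (limma, adjusted p = 2.0e-04 and 9.2e-05). The error is the limma standard error here and for every log2 change of a gene. Single libraries held 8 to 69 reads of Trp53cor1, so the size of each fall is known only roughly. The antisense gene AC167363.1 overlaps it, and strand use in counting was not given in the sources used here, so reads of the 2 genes cannot be told apart. Below, control means the negative-control GapmeR and knockdown the lincRNA-p21 GapmeR, and the p-values measure only the spread between these libraries, since the labels state no separate cultures or animals.

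**Figure D1:**
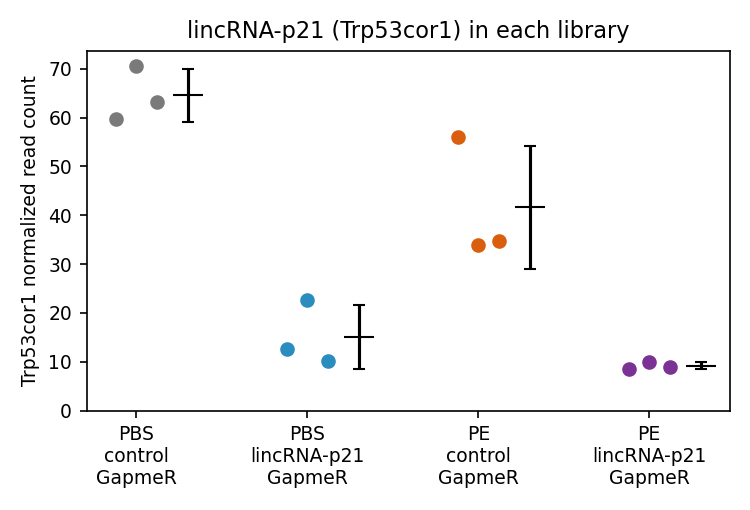
Normalised read count of Trp53cor1 in the 4 groups, with points for libraries and the mean ± SD (n = 3) beside them. The knockdown means were 15.1 in PBS and 9.16 in PE, against 64.5 and 41.6 in the controls.

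In control cells PE raised Nppb, which encodes the natriuretic peptide BNP, and Acta1, the skeletal alpha-actin of the fetal heart, while Myh7, the fetal myosin heavy chain, fell. Nppb (ENSMUSG00000029019.9, chromosome 4, 147985788 to 147987205) went from 2991 ± 637 to 21526 ± 1246, and Acta1 (ENSMUSG00000031972.6, chromosome 8, 123891769 to 123894751) from 184 ± 6.64 to 1072 ± 90.1. Their log2 changes were 2.87 ± 0.13 and 2.53 ± 0.11 (limma, adjusted p = 7.6e-12 and 4.7e-12). Myh7 (ENSMUSG00000053093.17, chromosome 14, 54970684 to 54994626) fell from 9501 ± 730 to 3790 ± 546, a log2 change of -1.33 ± 0.12 (limma, adjusted p = 8.0e-08), although it shares its locus with the noncoding Mhrt. Nppa, the gene of the other natriuretic peptide, rose by 0.51 ± 0.11, the adult myosin Myh6 by 0.89 ± 0.21 and the calcineurin target Rcan1 by 0.94 ± 0.10 (limma, adjusted p = 0.0014, 0.0030 and 4.4e-07). Cdkn1a, the cell cycle inhibitor p21, rose by 0.53 ± 0.12 (limma, adjusted p = 0.0030). Trp53cor1 was -0.66 ± 0.30 with PE and did not pass limma (adjusted p = 0.118), but it passed with values rescaled to the same total (-0.81, limma adjusted p = 0.047) and with limma-voom (-0.67, adjusted p = 0.031). Srsf3, a splicing factor beside the lincRNA, was 0.18 ± 0.12 and the adenosine receptor gene Adora2a 0.07 ± 0.28, neither called by limma (adjusted p = 0.30 and 0.90).

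**Figure D2:**
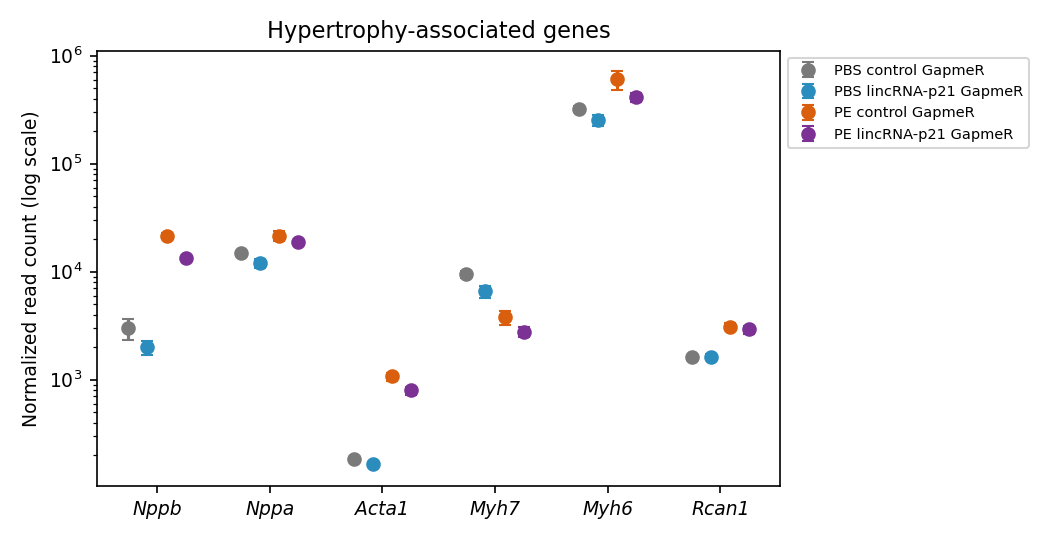
Normalised read count on a log axis of Nppb, Nppa, Acta1, Myh7, Myh6 and Rcan1 in the 4 groups, as mean with SD bars (n = 3). Nppb stood at 2991 in PBS controls, 21526 in PE controls and 13284 in PE with the knockdown.

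The largest rise with PE was in the chemokine gene Ccl6 (ENSMUSG00000018927.4, chromosome 11, 83587882 to 83593087), from 8.16 ± 2.83 to 352 ± 54.3. Its log2 change was 5.30 ± 0.34 (limma, adjusted p = 8.9e-10). Rgs16, a brake on G protein signalling, rose by 3.57 ± 0.21, Serpinb2 by 3.53 ± 0.29 and the prostaglandin synthase Ptgs2 by 3.38 ± 0.13. Krt18 rose by 3.31 ± 0.12, the BMP antagonist Grem1 by 3.18 ± 0.20, Hr by 3.11 ± 0.14 and the growth factor Hbegf by 2.85 ± 0.12. Among genes with a mean log2 CPM of at least 1 and no overlap between libraries, the transporter gene Abca8a (ENSMUSG00000041828.16, chromosome 11, 110025634 to 110095978) fell most, from 209 ± 15.9 to 11.5 ± 4.47. The growth factor Ptn (ENSMUSG00000029838.12, chromosome 6, 36714929 to 36810220) fell from 1587 ± 270 to 97.1 ± 10.2. Their log2 changes were -4.13 ± 0.27 and -4.01 ± 0.16 (limma, adjusted p = 1.2e-09 and 1.6e-12). Aldh3a1 (-3.97), Islr (-3.69), Steap4 (-3.68), Aspn (-3.51), Cacng6 (-3.49), Gdf10 (-3.44), Fmod (-3.42) and Gsta3 (-3.26) followed. Each gene of this paragraph had library values in PE that did not overlap those in PBS, a pattern that chance gives 10% of unchanged genes with 3 libraries against 3.

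PE changed 5543 of 21799 genes tested, 2742 higher and 2801 lower (limma, Benjamini-Hochberg adjusted p of 0.05). Rescaling values to the same total took the median of genes with a mean value of at least 50 from 0.01 to -0.15 and the share of lower calls from 50.5% to 71.9%. Of the 16 genes of the hypertrophic and fetal program, 10 rose and 2 fell, 11 and 2 when adjusted over the list alone, with a median of 0.62 (camera, adjusted p = 3.4e-07). The matricellular Ccn2 rose by 2.36 and the stress cytokine Gdf15 by 1.77. Of 21 immediate early and MAPK feedback genes 20 rose, and adjusted over the list alone 20 rose and 1 fell (median 1.10, camera adjusted p = 2.6e-16). Fosl1 rose by 2.72, Fos by 1.80, Fosl2 by 1.31 and the feedback inhibitor Spry4 by 1.27, although Fosl1 overlaps the higher Ccdc85b on the other strand. Of 16 NF-kB targets and cytokines 15 rose, also when adjusted over the list alone (median 1.22, camera adjusted p = 1.8e-15), with Lif at 2.34, Cxcl1 at 1.86 and Cxcl5 at 1.71. Of 17 angiogenic factors and adenosine receptors 10 rose and 1 fell, 10 and 2 when adjusted over the list alone (median 0.70, camera adjusted p = 1.2e-05), with Pdgfb at 2.12, Edn1 at 1.61, Adora1 at 1.54 and Apln at 1.49. Of 22 p53 targets 13 rose and 2 fell, 13 and 3 when adjusted over the list alone (median 0.40, camera adjusted p = 5.1e-05), with Plk2 at 1.83, Btg2 at 1.15 and Sesn1 at -1.21. These 5 lists held their camera calls with an estimated correlation.

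Genes for making ribosomes rose with PE and genes for making cholesterol fell. Of 19 ribosome biogenesis genes 17 rose, 18 when adjusted over the list alone (median 0.82, camera adjusted p = 4.1e-13), with Nolc1 at 1.10, Nop2 at 0.94 and Wdr43 at 0.87. Of 19 cholesterol genes 15 fell, 16 when adjusted over the list alone (median -0.64, camera adjusted p = 1.6e-10), with the sterol sensor partner Insig1 at -1.52, Dhcr7 at -1.30, Mvd at -1.05 and Lss at -0.79. Both calls held with an estimated correlation. Of 22 ribosomal proteins 18 rose, also when adjusted over the list alone (median 0.49, camera adjusted p = 1.6e-07), with adjusted p = 0.25 with an estimated correlation. Rpl6 rose by 0.61 and Rpl4 by 0.59.

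Markers of other heart cells moved in different directions. Of 12 fibroblast markers 9 fell and 2 rose, 9 and 3 when adjusted over the list alone (median -0.96, camera adjusted p = 1.2e-05), with the proteoglycan Lum at -2.66, Col15a1 at -2.09, Dpt at -1.88 and the transcription factor Tcf21 at -1.28. Of 14 endothelial markers 11 rose and 1 fell, also when adjusted over the list alone (median 1.10, camera adjusted p = 2.1e-09), with Cdh5 at 1.74, Flt1 at 1.54 and Pecam1 at 1.53. Both calls held with an estimated correlation. Of 15 leukocyte markers 9 rose, also when adjusted over the list alone (median 0.57, camera adjusted p = 3.1e-05), with adjusted p = 0.075 with an estimated correlation. The complement genes C1qc, C1qb and C1qa rose by 3.15, 2.68 and 2.48. Of 11 smooth muscle and pericyte markers 4 rose and 6 fell, also when adjusted over the list alone, with a median of -0.41 but a mean of -0.04 (camera, adjusted p = 0.64). Cnn1 rose by 2.32 and Myh11 fell by 1.52. Epicardial (2 of 10 higher, 3 lower, 3 and 3 when adjusted over the list alone), Schwann cell (1 of 6 higher, 3 lower, the same over the list alone) and erythroid markers (5 genes, no call) gave camera adjusted p = 0.61, 0.25 and 0.46.

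Sarcomere genes rose and ion channel genes fell with PE, and both calls were lost with an estimated correlation. Of 18 sarcomere genes 9 rose and 1 fell, 10 and 1 when adjusted over the list alone (median 0.37, camera adjusted p = 0.0035, adjusted p = 0.27 with an estimated correlation), with cardiac actin Actc1 at 1.25 and Myoz2 at 1.11. Of 22 calcium and ion channel genes 11 fell and 4 rose, 11 and 5 when adjusted over the list alone (median -0.34, camera adjusted p = 0.0093, adjusted p = 0.25 with an estimated correlation), with the potassium channel genes Kcnip2 at -2.12 and Kcnj3 at -1.53. Of 18 genes of glycolysis 8 rose and 2 fell, 9 and 2 when adjusted over the list alone (median 0.28, camera adjusted p = 7.9e-04, adjusted p = 0.23 with an estimated correlation), with the lactate transporter Slc16a3 at 1.33 and Hk2 at 1.05. Of 20 ATF4 targets of the integrated stress response 7 fell and 1 rose, 12 and 1 when adjusted over the list alone (median -0.31, camera adjusted p = 7.1e-04, adjusted p = 0.099 with an estimated correlation). The pseudokinase Trib3 fell by 1.75 and Pck2 by 0.82. Of 21 extracellular matrix genes 9 rose and 5 fell, 9 and 6 when adjusted over the list alone, with Tnc at 2.58, Thbs1 at 2.57 and Col3a1 at -2.09. Their median was 0.09, or -0.06 with values rescaled to the same total (extracellular matrix and remodelling, camera adjusted p = 0.026, adjusted p = 0.54 with an estimated correlation).

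Of 22 interferon-stimulated genes 7 rose and 1 fell with PE, 10 and 2 when adjusted over the list alone (median 0.53, camera adjusted p = 0.0093, adjusted p = 0.56 with an estimated correlation). Rsad2 rose by 1.12 and Stat2 fell by 0.62. The call was lost without PBS control replicate 2 (camera adjusted p = 0.095), PBS knockdown replicate 2 (0.058) or PE control replicate 1 (0.34). Of 15 endoplasmic reticulum chaperones and the unfolded protein response genes 5 fell, also when adjusted over the list alone (median -0.22, camera adjusted p = 0.021, adjusted p = 0.23 with an estimated correlation), with Herpud1 at -0.70 and Sel1l at -0.45. That call was lost in 6 of 12 leave-one-out fits, among them the one without PE control replicate 2 (-0.19, camera adjusted p = 0.10). The other lists were not called by camera. Calcineurin and MEF2 genes (4 of 21 higher, 4 lower) and adrenergic signalling genes (2 of 17 higher, 3 lower) gave the same counts when adjusted over the list alone (camera adjusted p = 0.61 and 0.54), with Hdac9 at -1.62 and Rgs5 at -1.76. Fatty acid genes (2 of 21 higher, 6 lower, 3 and 6 when adjusted over the list alone) had a median of 0.05 and a mean of -0.03 (camera, adjusted p = 0.61), with Pdk4 at 1.07 and Acadm at -0.82. NRF2 targets (4 of 16 higher, 4 lower, 5 and 4 when adjusted over the list alone) had a median of 0.06 and a mean of -0.09 (camera, Up, adjusted p = 0.77), with Hmox1 at 1.77 and Gstm1 at -1.19.

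HIF targets gave 6 of 16 higher and 4 lower with PE, 7 and 5 when adjusted over the list alone (camera, adjusted p = 0.64), with Adm at 0.99. Nuclear respiratory chain genes gave 3 of 26 lower, 1 when adjusted over the list alone (camera, adjusted p = 0.77), with Cox8b at -0.46. Mitochondrially encoded genes gave 1 of 13 lower, none when adjusted over the list alone (camera, adjusted p = 0.61). G2 and M phase genes gave 2 of 21 higher and 2 lower (camera, adjusted p = 0.31), and S phase genes 2 of 16 higher and 2 lower (camera, adjusted p = 0.77), the same adjusted over the list alone. Ccnb2 fell by 0.65 and Tyms rose by 0.53. The S phase median was -0.02 and its mean 0.03. Among 10 genes near Trp53cor1 on chromosome 17, 2 rose and 4 fell, the same adjusted over the list alone (camera, adjusted p = 0.56), with the kinase gene Pim1 at 0.63 and Cpne5 at -1.37. Among 9 genes of proteins reported to bind lincRNA-p21 or to act with KAP1, 3 rose, 4 when adjusted over the list alone, with Mdm2 at 0.74 and Prmt1 at 0.84 (camera, adjusted p = 0.055, and 0.042 without PE control replicate 1).

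**Figure D3:**
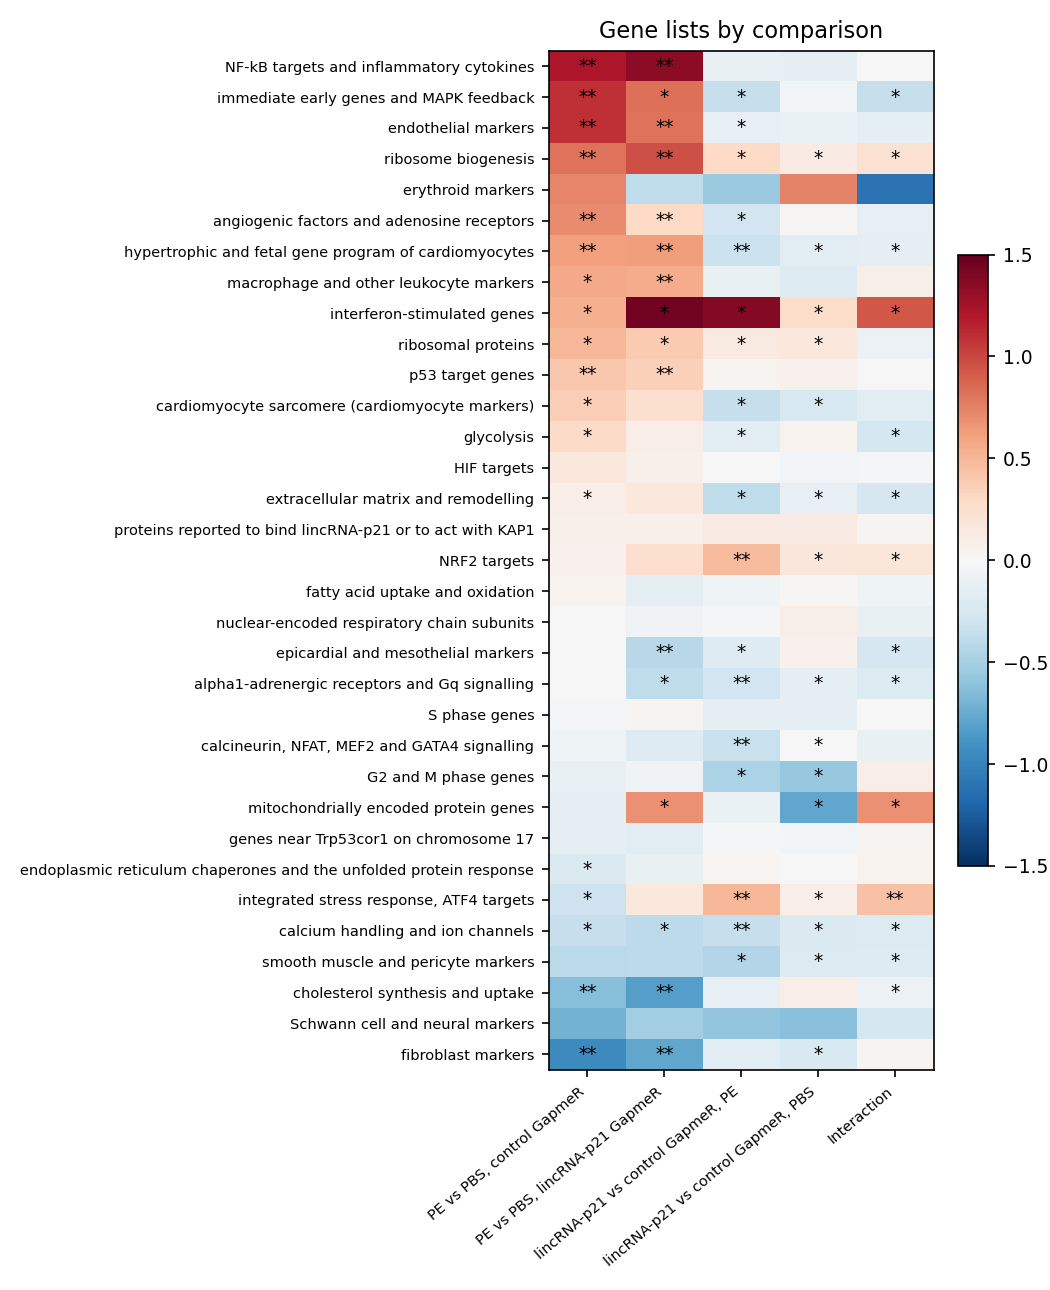
Median log2 change of each of the 33 lists (vertical) in the comparisons (horizontal), coloured from -1.5 to 1.5, with 1 star for a camera call and 2 stars where it also held with an estimated correlation. Interferon genes reached 1.38 with the knockdown in PE, and fibroblast markers -0.96 with PE.

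In PE the knockdown lowered Nppb, from 21526 ± 1246 to 13284 ± 156, and raised ATF4 targets. Interferon-stimulated genes rose by camera with a fixed correlation and by fry (adjusted p = 9.7e-20 and 5.5e-04). Camera with an estimated correlation gave adjusted p = 0.053. The log2 change of Nppb was -0.69 ± 0.13 (limma, adjusted p = 0.0011), a call kept in every leave-one-out fit. Acta1 fell from 1072 ± 90.1 to 794 ± 69.1 and Myh7 from 3790 ± 546 to 2766 ± 287, with log2 changes of -0.43 ± 0.11 and -0.45 ± 0.12 (limma, adjusted p = 0.013 and 0.017). Acta1 lost its call without PE control replicate 1 (-0.38, limma adjusted p = 0.076), PE control replicate 2 (0.060) or PE knockdown replicate 1 (0.061), and with values rescaled to the same total (0.062). Myh7 lost it without PE control replicate 1 (-0.34, limma adjusted p = 0.12) or 2 (0.051) and without PE knockdown replicate 2 (0.094) or 3 (0.072). Nppa was -0.18 ± 0.11, Rcan1 -0.09 ± 0.10, Cdkn1a -0.07 ± 0.12, Srsf3 -0.29 ± 0.12 and Adora2a -0.17 ± 0.28, none called by limma (adjusted p = 0.35, 0.64, 0.81, 0.13 and 0.80). Myh6 was -0.53 ± 0.21 (limma, adjusted p = 0.11), and count tests on the recovered reads called it lower (adjusted p = 0.010 with edgeR, 7.7e-04 with DESeq2 and 0.0085 with limma-voom).

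The steroid enzyme gene Hsd3b1 (ENSMUSG00000027871.17, chromosome 3, 98852194 to 98859794) rose most with the knockdown in PE, from 11.1 ± 1.54 to 435 ± 19.9. Its near-identical neighbour Hsd3b6 (ENSMUSG00000027869.15, chromosome 3, 98805504 to 98814443) rose from 18.3 ± 1.20 to 231 ± 1.54, and counting could split reads between the 2 genes. Their log2 changes were 5.18 ± 0.35 and 3.59 ± 0.32 (limma, adjusted p = 1.1e-08 and 2.7e-07). Trib3 (ENSMUSG00000032715.10, chromosome 2, 152337422 to 152344032) rose from 167 ± 12.1 to 968 ± 143, by 2.52 ± 0.12 (limma, adjusted p = 2.1e-10). Zdhhc23 rose by 2.22, the antiviral genes Rsad2, Ifit1, Mx2 and Ifit3b by 1.95, 1.90, 1.86 and 1.81, the peptide gene Adm2 by 1.91 and the deiodinase Dio2 by 1.78. Among genes with a mean log2 CPM of at least 1 and no overlap between libraries, Ralgapa2 (ENSMUSG00000037110.21, chromosome 2, 146239879 to 146512344), a regulator of Ral GTPases, fell most, from 1213 ± 71.1 to 238 ± 15.1. The calcineurin catalytic subunit gene Ppp3ca (ENSMUSG00000028161.18, chromosome 3, 136670124 to 136937727) fell from 1854 ± 47.7 to 397 ± 37.9. Their log2 changes were -2.34 ± 0.12 and -2.22 ± 0.11 (limma, adjusted p = 5.4e-10 and 2.1e-10). Rgs17 (-2.28), Maml3 (-2.28), Sema5a (-2.22), Tmem131l (-2.14), Urm1 (-2.08), the neuregulin receptor Erbb4 (-2.06), Sox5 (-2.04) and Amot (-1.99) also fell, all with library values that did not overlap, as 10% of unchanged genes would by chance.

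The knockdown changed 2553 genes in PE, 997 higher and 1556 lower (limma). The count was 1671 without PE knockdown replicate 2, 1701 without PE control replicate 2 and 4672 without 3 distant libraries, and the share of lower calls went from 60.9% to 42.3% with values rescaled to the same total. Of 22 interferon-stimulated genes 17 rose, 19 when adjusted over the list alone (median 1.38, camera adjusted p = 9.7e-20), with adjusted p = 0.053 with an estimated correlation. Ifit3 rose by 1.74, Cxcl10 by 1.68 and Oasl2 by 1.47. Of 20 ATF4 targets 15 rose, 16 when adjusted over the list alone (median 0.50, camera adjusted p = 1.1e-13), with Atf5 at 1.20 and Nupr1 at 1.08. Of 16 NRF2 targets 8 rose, and adjusted over the list alone 10 rose and 1 fell (median 0.47, camera adjusted p = 7.5e-07), with Osgin1 at 1.35, heme oxygenase Hmox1 at 0.72 and Gsta4 at 0.70. The last 2 lists held with an estimated correlation. Of 19 ribosome biogenesis genes 6 rose and 1 fell, 11 and 1 when adjusted over the list alone (median 0.30, camera adjusted p = 1.1e-04, adjusted p = 0.13 with an estimated correlation), with Nop56 at 0.62 and Polr1a at -0.83. No gene of 22 ribosomal proteins was called by limma over all genes or adjusted over the list alone, with a median of 0.14 (camera, adjusted p = 0.020, adjusted p = 0.56 with an estimated correlation), lost in 7 of 12 leave-one-out fits, the highest without PE knockdown replicate 2 (0.23).

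Lists of the hypertrophic program, of adrenergic and calcineurin signalling and of ion channels had lower medians with the knockdown in PE. Of 16 hypertrophic and fetal genes 7 fell, also when adjusted over the list alone (median -0.32, camera adjusted p = 5.5e-06), with Xirp2 at -1.05, Ccn2 at -0.70 and Fhl1 at -0.61. Of 22 calcium and ion channel genes 10 fell, 12 when adjusted over the list alone (median -0.35, camera adjusted p = 2.7e-10), with Kcnd2 at -1.74, the sodium-calcium exchanger Slc8a1 at -1.56 and the L-type channel Cacna1c at -1.42. Of 21 calcineurin, NFAT and MEF2 genes 7 fell and 1 rose, 12 and 1 when adjusted over the list alone (median -0.34, camera adjusted p = 3.3e-07), with Mef2c at -1.22 and Mef2a at -1.20. Of 17 adrenergic and Gq genes 6 fell, 8 when adjusted over the list alone (median -0.29, camera adjusted p = 1.2e-05), with the kinase genes Prkca and Prkce at -1.78 and -1.38. These 4 lists held their camera calls with an estimated correlation. All 7 calcineurin genes and all 6 adrenergic genes that fell, and 6 of the 10 ion channel genes, span over 100 kb of the genome. Members up to 100 kb and over 100 kb had medians of -0.05 and -0.74 in the adrenergic list, -0.23 and -0.60 in the calcineurin list and -0.29 and -1.22 in the ion channel list, a split made after the values were seen. The hypertrophic list has no member over 100 kb.

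Of 21 G2 and M phase genes 14 fell with the knockdown in PE, 19 when adjusted over the list alone (median -0.48, camera adjusted p = 1.4e-10, adjusted p = 0.11 with an estimated correlation), with Cenpe and Ttk at -0.72 and Top2a at -0.55. Of 21 extracellular matrix genes 11 fell, 12 when adjusted over the list alone (median -0.38, camera adjusted p = 2.2e-08, adjusted p = 0.11 with an estimated correlation), with Thbs1 at -0.61 and Tnc at -0.51. Of 21 immediate early genes 7 fell and 1 rose, 12 and 1 when adjusted over the list alone (median -0.35, camera adjusted p = 7.0e-05, adjusted p = 0.24 with an estimated correlation), with Egr1 at -0.96. Of 18 sarcomere genes 3 fell, 9 when adjusted over the list alone (median -0.34, camera adjusted p = 9.7e-06, adjusted p = 0.11 with an estimated correlation), with Myom1 at -0.85 and Tcap at -0.78. Of 11 smooth muscle markers 4 fell, 7 when adjusted over the list alone (median -0.44, camera adjusted p = 2.7e-04, adjusted p = 0.11 with an estimated correlation), with Lmod1 at -0.83 and Pdgfrb at -0.69.

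In 4 further lists the camera call with the knockdown in PE was lost in leave-one-out fits. Of 18 genes of glycolysis 1 fell, 4 when adjusted over the list alone (median -0.16, camera adjusted p = 0.0083, adjusted p = 0.25 with an estimated correlation), with Pfkl at -0.44 and the list's call lost without PE control replicate 1 (0.11) or 2 (0.059) or PE knockdown replicate 1 (0.16). Of 17 angiogenic factors and adenosine receptors 4 fell and 1 rose, also when adjusted over the list alone (median -0.29, camera adjusted p = 0.030, adjusted p = 0.11 with an estimated correlation), with Adm at -0.66 and the call lost in 11 of 12 leave-one-out fits (0.13 without PE knockdown replicate 3). Of 14 endothelial markers 3 fell, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.028, adjusted p = 0.11 with an estimated correlation), with Ptprb at -0.80 and the call lost in 5 of 12 fits (0.11 without PE control replicate 1). Of 10 epicardial and mesothelial markers 1 fell, 2 when adjusted over the list alone (median -0.20, camera adjusted p = 0.030, adjusted p = 0.11 with an estimated correlation), with Tbx18 at -0.47 and the call lost in all 12 fits (0.12 without PE control replicate 1).

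The remaining lists were not called by camera with the knockdown in PE. Of 22 p53 targets 3 rose and 2 fell, 4 and 2 when adjusted over the list alone, with Mdm2 at 0.50 and Btg2 at -0.49 (camera, adjusted p = 0.54). Among partners of lincRNA-p21, 2 of 9 rose, and 2 rose and 1 fell adjusted over the list alone, with Trim28, the gene of KAP1, at 0.39 (camera, adjusted p = 0.11). The 10 neighbours of Trp53cor1 held no limma call over all genes or adjusted over the list alone (camera, Up, adjusted p = 0.90, with a median and mean of -0.01). Fibroblast markers (2 of 12 lower, Ddr2 at -0.54), leukocyte markers (15 genes, median -0.11, no call) and erythroid markers (5 genes, no call) gave the same counts adjusted over the list alone (camera adjusted p = 0.069, 0.74 and 0.67). Schwann cell markers gave 1 of 6 lower, 2 adjusted over the list alone, with Cdh19 at -2.09 (camera, adjusted p = 0.069). S phase genes gave 1 of 16 higher and 1 lower, 1 and 2 adjusted over the list alone, with Mcm7 at 0.40 (camera, adjusted p = 0.25). NF-kB targets gave 1 of 16 higher and 2 lower, 1 and 3 adjusted over the list alone, with Ccl5 at 0.86, a call lost without PE knockdown replicate 2 (0.75, limma adjusted p = 0.11), and camera adjusted p = 0.26. Cholesterol genes gave 2 of 19 lower, 3 adjusted over the list alone, with Lss at -0.47 (camera, adjusted p = 0.12).

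Metabolic lists held few calls with the knockdown in PE. Fatty acid genes gave 1 of 21 lower, with Hadh at -0.46, and HIF targets 1 of 16 higher and 2 lower, with Ero1l at 1.07, both the same adjusted over the list alone (camera adjusted p = 0.17 and 0.87). The HIF median was 0.00 and its mean -0.02. Nuclear respiratory chain genes (26 measured, Ndufa4 at 0.10), mitochondrially encoded genes (13 measured, mt-Nd1 at -0.10) and chaperone genes of the endoplasmic reticulum (15 measured, Hspa5 at 0.15) held no limma call over all genes or adjusted over the list alone (camera adjusted p = 0.74, 0.80 and 0.34).

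Of the 5543 genes changed by PE, 562 moved the opposite way with the knockdown in PE, 346 up then down and 216 down then up, where chance gives 196 and 128 (limma). Another 524 moved the same way, 168 up and 356 down, where chance gives 125 and 200. Ccn2 and Nppb were among those that rose with PE and fell with the knockdown, and Trib3 among those that fell and then rose. Across 12113 genes, which are not independent replicates, Pearson's r of the 2 effects was 0.0034. For r, 20 simulated draws with an unchanged knockdown gave a mean of -0.133 from the shared controls alone. The PE controls enter both comparisons, which cannot be split with 3 libraries, so part of the excess can come from shared controls. Chance was also taken over all 21799 genes tested, low ones included. With a filter of CPM of at least 1 in 3 libraries, 14053 genes kept 89.6% of the PE calls and 94.7% of the knockdown calls. Over such genes the chance counts would be higher, so these counts alone show no excess. The count was 336 without PE control replicate 2, 340 without PE control replicate 1, 370 without PE knockdown replicate 2 and 862 without PBS knockdown replicate 2 for PE-changed genes moved the opposite way by the knockdown in PE.

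In PBS the knockdown lowered Sema5a, Ralgapa2 and Ppp3ca most among genes with a mean log2 CPM of at least 1 and no overlap between libraries. Sema5a, a guidance molecule gene (ENSMUSG00000022231.11, chromosome 15, 32244810 to 32696341), fell from 1364 ± 11.5 to 196 ± 29.0, Ralgapa2 from 1326 ± 71.8 to 210 ± 39.3 and Ppp3ca from 2064 ± 177 to 335 ± 35.8. Their log2 changes were -2.80 ± 0.13, -2.67 ± 0.12 and -2.62 ± 0.11 (limma, adjusted p = 6.8e-11, 6.8e-11 and 2.3e-11). Tmem131l (-2.03), Urm1 (-1.96), Nckap5 (-1.93), Erbb4 (-1.91), Diaph3 (-1.85), Sox5 (-1.77) and Plxnc1 (-1.76) followed within these limits. Rgs17, under the CPM limit, was -2.24 ± 0.20 (limma, adjusted p = 9.4e-07). Urm1 (ENSMUSG00000069020.10, chromosome 2, 29820075 to 29845002) encodes a ubiquitin-like modifier. The transcription factor gene Pou3f1 (ENSMUSG00000090125.4, chromosome 4, 124656807 to 124660655) rose most within the same limits, from 28.8 ± 1.96 to 106 ± 17.3, by 1.83 ± 0.19 (limma, adjusted p = 5.4e-06). Under the CPM limit Hsd3b1 rose more, from 9.26 ± 7.42 to 187 ± 23.2, and Hsd3b6 from 4.46 ± 3.52 to 64.3 ± 11.9, both looked up after the values were seen. Their log2 changes were 4.47 ± 0.35 and 3.75 ± 0.32 (limma, adjusted p = 1.6e-07 and 3.8e-07). Mcpt4 rose by 1.21, Kcnj4 by 1.19 and Fam69b by 0.95, all kept in every leave-one-out fit. Plppr3 (1.03) lost its call without PBS control replicate 1 (0.99, limma adjusted p = 0.054), and it lies antisense to the far higher Ptbp1. Mir6236 (1.00), Aoc2 (0.95) and Rnf227 (0.95) lost theirs without PBS control replicate 3 (0.89, limma adjusted p = 0.16), PBS control replicate 2 (0.66, 0.14) and PBS control replicate 3 (0.80, 0.12). All these genes had library values that did not overlap, which chance gives 10% of unchanged genes.

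Nppb was 2991 ± 637 in PBS controls and 1990 ± 301 with the knockdown, a log2 change of -0.58 ± 0.13 (limma, adjusted p = 0.012) that lost its call without PBS control replicate 2 (-0.41, limma adjusted p = 0.070) or PBS knockdown replicate 3 (0.054). Myh7 fell with a log2 change of -0.54 ± 0.12 (limma, adjusted p = 0.012), lost without PBS control replicate 2 (-0.50, 0.053) or 3 (0.063) or PBS knockdown replicate 3 (0.053). Nppa was -0.32 ± 0.11 (limma, adjusted p = 0.10), and it was called lower by DESeq2 (adjusted p = 0.013) and limma-voom (0.044). Acta1 was -0.15, Myh6 -0.36, Rcan1 0.01, Cdkn1a -0.10, Srsf3 -0.17 and Adora2a -0.21, none called by limma (adjusted p = 0.51, 0.39, 0.96, 0.73, 0.50 and 0.76). The interaction of Acta1, called in PE and not in PBS, was -0.28 ± 0.15 (limma, adjusted p = 0.58).

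In PBS the knockdown changed 997 genes, 297 higher and 700 lower (limma), with 510 without PBS control replicate 3 and 558 without PBS control replicate 1. With only the 6 libraries compared it changed 392, 58 higher and 334 lower, and without 3 distant libraries 1865, 733 higher and 1132 lower (limma). The lower share was 70.2%, or 85.2% and 60.7% in these 2 fits and 51.0% with values rescaled to the same total. Of the 997 genes 680, or 68.2%, moved the same way in PE, 132 up and 548 down. Chance over all genes tested, low ones included, gives 13.6 and 49.97. None was called in the opposite direction by limma. Of 21 G2 and M phase genes 14 fell, 18 when adjusted over the list alone (median -0.57, camera adjusted p = 1.8e-16, adjusted p = 0.14 with an estimated correlation), with Nusap1 at -0.79 and the proliferation marker Mki67 at -0.77. Of 22 calcium and ion channel genes 6 fell, 10 when adjusted over the list alone (median -0.22, camera adjusted p = 9.8e-06, adjusted p = 0.15 with an estimated correlation), with Slc8a1 at -1.41. Of 21 calcineurin and MEF2 genes 5 fell, also when adjusted over the list alone, with a mean of -0.31 and a median of -0.01, which was 0.06 when rescaled (camera, adjusted p = 3.8e-04, adjusted p = 0.17 with an estimated correlation). Mef2a fell by 1.09. Of 13 mitochondrially encoded protein genes 3 fell, 11 when adjusted over the list alone (median -0.77, camera adjusted p = 3.2e-07, adjusted p = 0.22 with an estimated correlation), with mt-Co2 at -0.77, lost without PBS control replicate 1 (-0.59, limma adjusted p = 0.17). Mitochondrial genes held 10.7% of reads in PBS control replicate 2 and 4.33% in PBS knockdown replicate 2, both among the 3 distant libraries, and without these 3 the median of the mitochondrially encoded protein genes was -0.40 (camera, adjusted p = 0.0018).

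Of 18 sarcomere genes 2 fell with the knockdown in PBS, 5 when adjusted over the list alone (median -0.24, camera adjusted p = 9.8e-04, adjusted p = 0.27 with an estimated correlation), with Myom1 and Tcap at -0.68. Of 16 hypertrophic and fetal genes 4 fell and 1 rose, 6 and 1 when adjusted over the list alone (median -0.16, camera adjusted p = 0.0076, adjusted p = 0.17 with an estimated correlation), with Xirp2 at -1.20 and Gdf15 at 0.80. Of 17 adrenergic genes 2 fell, 5 when adjusted over the list alone (median -0.13, camera adjusted p = 0.018, adjusted p = 0.20 with an estimated correlation), with Prkca at -1.42. The 2 adrenergic and the 5 calcineurin genes that fell in PBS all span over 100 kb. Members up to 100 kb and over 100 kb had medians of 0.05 and -0.42 in the adrenergic list and 0.01 and -0.39 in the calcineurin list. In the ion channel list they were -0.22 and -0.84, a split made after the values were seen. Of 12 fibroblast markers 2 fell, 5 when adjusted over the list alone (median -0.23, camera adjusted p = 0.0076, adjusted p = 0.14 with an estimated correlation), with Ddr2 at -0.52. Of 16 NRF2 targets 2 rose, 4 when adjusted over the list alone (median 0.17, camera adjusted p = 0.0024, adjusted p = 0.14 with an estimated correlation), with Srxn1 at 0.41, lost without PBS control replicate 3 (0.39, limma adjusted p = 0.073). Of 20 genes of the integrated stress response, ATF4 targets, 2 rose, 4 when adjusted over the list alone (median 0.10, camera adjusted p = 0.0094, adjusted p = 0.24 with an estimated correlation), with Atf5 at 0.67 and the call lost without PBS knockdown replicate 2 (0.074). No list of this comparison held its call with an estimated correlation.

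Interferon-stimulated genes had a median of 0.28 with the knockdown in PBS (22 measured, camera adjusted p = 0.0072, adjusted p = 0.46 with an estimated correlation), with no limma call over all genes or adjusted over the list alone, and the camera call was lost without PBS control replicate 2 (0.11) or PBS knockdown replicate 1 (0.12). Ifit1 was 0.56 ± 0.19 (limma, adjusted p = 0.12), called only without PBS knockdown replicate 3 (0.77, limma adjusted p = 0.033). The 22 ribosomal proteins, with no limma call over all genes or adjusted over the list alone, had a median of 0.16 (camera, adjusted p = 8.1e-04, adjusted p = 0.41 with an estimated correlation), lost without PBS knockdown replicate 1 (0.20). The 3 camera calls nearest the threshold were lost in at least 10 of 12 leave-one-out fits and with an estimated correlation. They were extracellular matrix and remodelling (21 genes, no limma call, median -0.12, camera adjusted p = 0.049, adjusted p = 0.49 with an estimated correlation, 0.46 without PBS knockdown replicate 1), smooth muscle and pericyte markers (1 of 11 lower, 2 adjusted over the list alone, median -0.21, camera adjusted p = 0.047, adjusted p = 0.37 with an estimated correlation, 0.27 without that library) and ribosome biogenesis (19 genes, no limma call, 1 higher and 1 lower adjusted over the list alone, median 0.13, camera adjusted p = 0.047, adjusted p = 0.41 with an estimated correlation, 0.51 without that library).

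The other lists were not called by camera with the knockdown in PBS. Immediate early genes (1 of 21 higher, Dusp4 at 0.53), HIF targets (2 of 16 higher, 1 lower), p53 targets (1 of 22 higher, Gdf15), partners of lincRNA-p21 (1 of 9 higher, Trim28 at 0.34) and S phase genes (1 of 16 lower, Ccne2 at -0.85) gave the same counts adjusted over the list alone (camera adjusted p = 0.51, 0.99, 0.23, 0.082 and 0.13). Fatty acid genes gave 1 of 21 lower, 2 adjusted over the list alone, glycolysis 1 of 18 higher, 2 adjusted over the list alone, with the glucose transporter Slc2a1 at 0.43 (camera adjusted p = 0.65 and 0.15). Angiogenic genes gave 1 of 17 higher and 3 lower, 1 and 4 adjusted over the list alone, and endothelial markers 1 of 14 lower, 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.38 and 0.51), with Fgf2 at -0.57 and Ptprb at -0.51. Of 15 leukocyte markers C1qc alone rose, from 6.75 ± 1.72 to 21.2 ± 5.03 (1 also adjusted over the list alone, camera adjusted p = 0.23). Limma called no gene of the respiratory chain, neighbour, erythroid, epicardial, Schwann cell, NF-kB, chaperone and cholesterol lists (camera adjusted p = 0.18, 0.95, 0.23, 0.23, 0.13, 0.13, 0.65 and 0.19). Adjusted over the list alone, 1 epicardial gene was higher, and 1 Schwann cell gene was higher and 2 lower. Signs differed between median, mean and camera for neighbours (-0.04, 0.04, Up), HIF targets (-0.05, -0.05, Up), fatty acid genes (0.01, 0.01, Down), angiogenic genes (0.02, -0.08, Down) and chaperones (-0.00, 0.02, Up).

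Genes with long genomic spans, grouped after the values were seen, fell with the knockdown in both media. Of the 1556 genes lower in PE, 787 (50.6%) span over 100 kb, and of the 700 lower in PBS 390 (55.7%), against 10.7% of all genes tested, low ones included. Among protein-coding genes with a mean value of at least 50, limma called 80.5% of those over 400 kb lower in PE and 4.35% of those up to 10 kb. In PBS these shares were 56.7% and 1.24%. The median log2 change of protein-coding genes over 400 kb was -0.82 in PE and -0.55 in PBS, and of those up to 10 kb 0.05 and 0.11. A score per library, the median deviation of 613 genes over 200 kb from their means less that of 6441 genes under 30 kb, was 0.321 ± 0.0166 in PBS controls, -0.112 ± 0.0904 in PBS with the knockdown, 0.208 ± 0.0142 in PE controls and -0.428 ± 0.0892 in PE with the knockdown. Ppp3ca, Ralgapa2 and Sema5a are such long genes, whereas Urm1 spans 24928 bases.

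**Figure D4:**
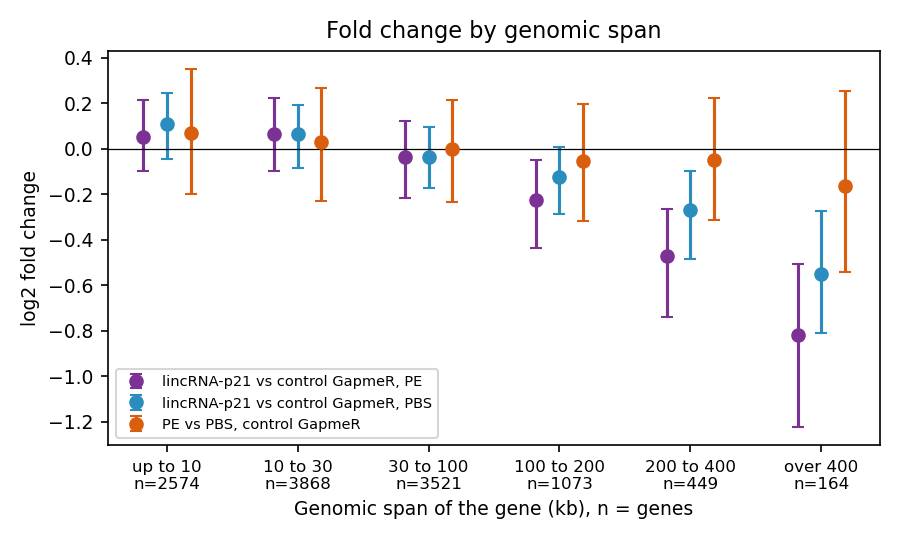
Median log2 change (vertical, bars show the interquartile range over genes) by genomic span of protein-coding genes in kb (horizontal) for PE against PBS and the knockdown in PE and in PBS. Genes over 400 kb had medians of -0.16, -0.82 and -0.55.

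With the knockdown in place, PE still raised Nppb and Acta1, by 2.75 ± 0.13 and 2.25 ± 0.11 (limma, adjusted p = 2.1e-11 and 2.6e-11), and lowered Myh7, with a log2 change of -1.25 ± 0.12 (limma, adjusted p = 2.1e-07). Nppa rose by 0.66, Rcan1 by 0.83 and Cdkn1a by 0.56 (limma, adjusted p = 1.2e-04, 2.1e-06 and 0.0017). Myh6 rose by 0.71 (limma, adjusted p = 0.013), lost without PBS knockdown replicate 3 (0.66, limma adjusted p = 0.053). Trp53cor1 was -0.59, Srsf3 0.06 and Adora2a 0.11, none called by limma (adjusted p = 0.15, 0.76 and 0.82). Serpinb2 rose by 3.65, Grem1 by 3.63, Ptgs2 by 3.33, Rsad2 by 2.98, Cxcl10 by 2.95, Krt18 and Bmp2 by 2.81 and Hbegf by 2.75, and Rgs16 rose from 50.6 ± 6.24 to 542 ± 38.0. Ptn (-3.89), Cacng6 (-3.74), Gdf10 (-3.69), Aldh3a1 (-3.48), Cygb (-3.26), Islr (-3.04), Fmod (-3.03), Selenbp1 (-2.90), Tmem45a (-2.89) and Steap4 (-2.84) fell, all without overlap between libraries, as 10% of unchanged genes would by chance. PE changed 5967 genes in these cells, 2918 higher and 3049 lower (limma), a lower share of 51.1%, or 69.2% with values rescaled to the same total. Of the 5543 genes changed by PE in control cells 68.6% were also called here, 3796 in the same direction and 9 in the opposite one. Those in the same direction were 1847 up and 1949 down, where chance over all genes tested, low ones included, gives 367 and 392.

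Interferon-stimulated genes rose with PE in knockdown cells, 18 of 22 and 20 when adjusted over the list alone (median 1.45, camera adjusted p = 2.1e-12, adjusted p = 0.082 with an estimated correlation), with Ifit3 at 2.39 and Ifit1 at 1.87. Of 16 NF-kB targets 15 rose, 16 when adjusted over the list alone (median 1.34, camera adjusted p = 7.0e-15). Of 19 ribosome biogenesis genes 18 rose, 19 when adjusted over the list alone (median 0.97, camera adjusted p = 9.2e-15), with Nop56 at 1.35. Of 19 cholesterol genes 17 fell, 18 when adjusted over the list alone (median -0.82, camera adjusted p = 2.3e-13), with Insig1 at -1.95. Of 16 hypertrophic genes 9 rose and 2 fell, 9 and 3 when adjusted over the list alone (median 0.63, camera adjusted p = 5.1e-05), with Ccn2 at 1.81. The last 4 lists held with an estimated correlation. Of 21 immediate early genes 17 rose, also when adjusted over the list alone (median 0.82, camera adjusted p = 3.6e-11, adjusted p = 0.082 with an estimated correlation), with Myc at 1.40. Of 22 ribosomal proteins 14 rose, 17 when adjusted over the list alone (median 0.39, camera adjusted p = 3.8e-06, adjusted p = 0.27 with an estimated correlation).

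Cell type markers also changed with PE in knockdown cells. Endothelial markers rose (10 of 14 and 1 lower, also when adjusted over the list alone, median 0.81, camera adjusted p = 2.0e-07), with Emcn at 2.01. Fibroblast markers fell (8 of 12 and 2 higher, 9 and 2 when adjusted over the list alone, median -0.78, camera adjusted p = 9.4e-06), with Lum at -2.40. Leukocyte markers rose (10 of 15, also when adjusted over the list alone, median 0.56, camera adjusted p = 3.8e-06), with C1qa at 2.67. Epicardial markers fell (7 of 10 and 2 higher, also when adjusted over the list alone, median -0.42, camera adjusted p = 0.0063), with Muc16 at -2.02. The p53 targets rose (12 of 22 and 2 lower, 13 and 2 when adjusted over the list alone, median 0.36, camera adjusted p = 1.1e-04), with Plk2 at 1.80, and so did angiogenic genes (8 of 17 and 2 lower, also when adjusted over the list alone, median 0.30, camera adjusted p = 3.6e-04), with Pgf at 1.90. These 6 lists held with an estimated correlation. Calcium and ion channel genes fell (10 of 22 and 3 higher, 13 and 3 when adjusted over the list alone, median -0.39, camera adjusted p = 2.0e-05), with adjusted p = 0.071 with an estimated correlation. Adrenergic genes fell (8 of 17 and 1 higher, 10 and 1 when adjusted over the list alone, median -0.39, camera adjusted p = 0.0040), also with adjusted p = 0.071 with an estimated correlation. The mitochondrially encoded protein genes rose (4 of 13, 8 when adjusted over the list alone, median 0.69, camera adjusted p = 0.0094, adjusted p = 0.43 with an estimated correlation), lost without PBS knockdown replicate 1 (0.053) or 2 (0.15) or PE knockdown replicate 1 (0.11) and without 3 distant libraries (median 0.22, camera adjusted p = 0.31).

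The other lists were not called by camera for PE in knockdown cells. NRF2 targets gave 8 of 16 higher and 3 lower, 9 and 3 adjusted over the list alone, with Hmox1 at 2.17 (camera, adjusted p = 0.066). Sarcomere genes gave 7 of 18 higher and 1 lower, 8 and 1 adjusted over the list alone, with Actc1 at 1.08 (camera, adjusted p = 0.051). Calcineurin genes gave 2 of 21 higher and 8 lower, 3 and 8 adjusted over the list alone, with Nfatc4 at -1.57 (camera, adjusted p = 0.14). ATF4 targets gave 7 of 20 higher and 3 lower, 9 and 4 adjusted over the list alone, with Slc7a11 at 0.59 (camera, adjusted p = 0.18). Fatty acid genes (3 of 21 higher, 6 lower, 4 and 6 adjusted over the list alone), glycolysis (5 of 18 higher, 3 lower, 5 and 4 over the list alone), HIF targets (5 of 16 higher, 4 lower, 6 and 4 over the list alone) and extracellular matrix genes (9 of 21 higher, 7 lower, 9 and 8 over the list alone) gave camera adjusted p = 0.18, 0.39, 0.62 and 0.31, with Col3a1 at -2.18. Respiratory chain (2 of 26 lower), neighbour (2 of 10 higher, 2 lower), partner (3 of 9 higher), smooth muscle (3 of 11 higher, 6 lower), erythroid (5 genes, no call), Schwann cell (2 of 6 lower), G2 and M phase (1 of 21 higher, 1 lower), S phase (2 of 16 higher) and chaperone genes (3 of 15 lower) gave the same counts adjusted over the list alone (camera adjusted p = 0.16, 0.43, 0.062, 0.19, 0.73, 0.11, 0.58, 0.62 and 0.11).

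The knockdown acted differently in PE than in PBS on 12 genes, all with a more positive change in PE (limma, interaction), although some alternative fits gave both directions. PE lowered Trib3 in control cells, from 561 to 167, and with the knockdown it stood at 768 in PBS and 968 in PE, an interaction of 2.08 ± 0.17 (limma, adjusted p = 6.2e-06). Ifit3b (ENSMUSG00000062488.10, chromosome 19, 34607970 to 34613401) and Ifit3 (ENSMUSG00000074896.4, chromosome 19, 34583531 to 34588731), near-identical antiviral genes whose reads counting could split, had interactions of 1.94 ± 0.26 and 1.85 ± 0.26 (limma, adjusted p = 0.0067 and 0.0083). These 3 kept their calls in every leave-one-out fit. Iigp1 (1.91) and Zdhhc23 (1.87, limma adjusted p = 0.011 for both) were lost without PBS control replicate 3 (0.051 for both), and Iigp1 also without PE control replicate 2 (0.063). Rsad2 (ENSMUSG00000020641.17, chromosome 12, 26442746 to 26456452), at 1.86 (limma, adjusted p = 0.026), was lost in 7 of 12 fits (0.15 without PE knockdown replicate 2), Ifi204 (1.55, 0.026) in 9 (0.12 without PE control replicate 2), Cxcl10 (1.37, 0.020), which overlaps the higher Art3 on the other strand, in 5 (0.13 without PE knockdown replicate 2), Igfbp5 (1.20, 0.026) in 6 (0.12 without PE control replicate 2) and Irgm2 (1.19, 0.033), which overlaps Igtp on the same strand, in 9 (0.17 without PE knockdown replicate 2). With the replicate block Igfbp5 and Irgm2 lost their calls (limma, adjusted p = 0.060 and 0.064). Gbp2 (1.12) and Dtx3l (0.84), outside the naming rule fixed before, were looked up after the values were seen. The count ran from 3 without PBS control replicate 3 to 22 without PE control replicate 1, with 2143 genes at unadjusted p under 0.05, and it was 13 with edgeR and 13 with limma-voom. DESeq2 gave 132, 60 higher and 72 lower, and the fit without 3 distant libraries 143, 74 higher and 69 lower (limma). With the GC trend removed 28 were higher and 5 lower. Without PBS knockdown replicate 1, PBS knockdown replicate 2 or PE knockdown replicate 1, 18, 19 and 13 were higher, each with 2 lower (limma).

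**Figure D5:**
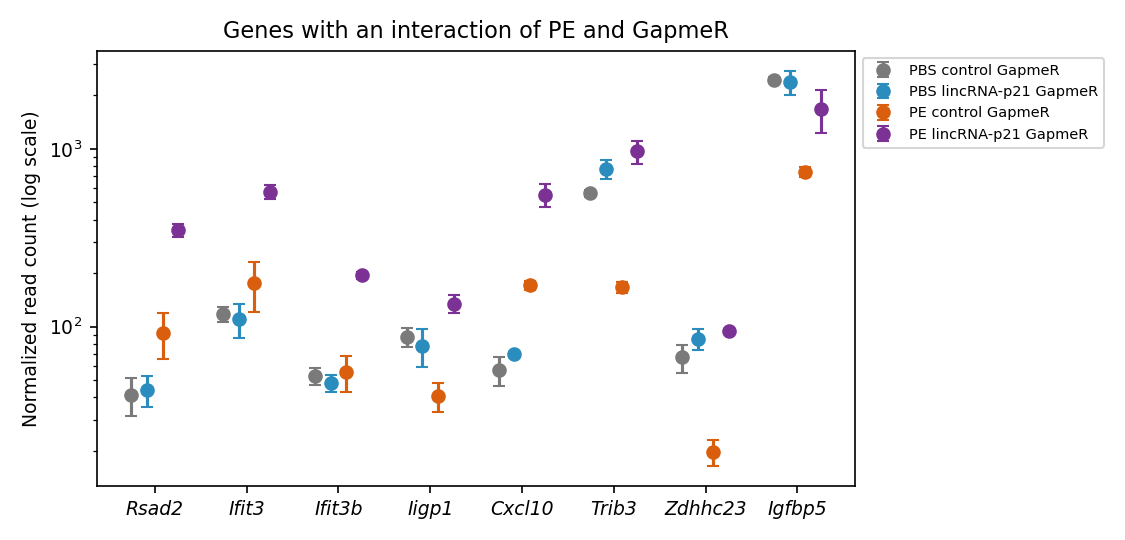
Normalised read count on a log axis of Rsad2, Ifit3, Ifit3b, Iigp1, Cxcl10, Trib3, Zdhhc23 and Igfbp5 in the 4 groups, as mean with SD bars (n = 3). Rsad2 stood at 41.5, 43.9, 92.2 and 349 in PBS controls, PBS with the knockdown, PE controls and PE with the knockdown.

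For lists, the interaction of the 22 interferon-stimulated genes had a median of 0.93 (3 called, 15 when adjusted over the list alone, camera adjusted p = 2.4e-18, adjusted p = 0.081 with an estimated correlation). That of 20 ATF4 targets was 0.44 (1 called, 9 when adjusted over the list alone, camera adjusted p = 2.1e-12), the only list that held with an estimated correlation. Limma called no gene in the other lists. Adjusted over the list alone, 4 NRF2 targets and 2 mitochondrially encoded genes were higher, 2 genes each of the immediate early, glycolysis, matrix and epicardial lists were lower, and so was 1 gene each of the hypertrophic, ion channel and ribosome biogenesis lists. The interactions of Nppa (0.14), Nppb (-0.12), Myh7 (0.09), Myh6 (-0.18), Rcan1 (-0.11), Cdkn1a (0.03), Srsf3 (-0.12), Adora2a (0.04), Trp53cor1 (0.06), Ppp3ca (0.40) and Mki67 (0.27) were not called by limma (adjusted p = 0.80, 0.88, 0.90, 0.88, 0.84, 0.97, 0.86, 0.98, 0.98, 0.41 and 0.70). Camera did not call the calcineurin (adjusted p = 0.059), endothelial (0.062), sarcomere (0.12), respiratory chain (0.12), erythroid (0.12), angiogenic (0.18), fatty acid (0.39), G2 and M phase (0.43), chaperone (0.61), Schwann cell (0.65), ribosomal protein (0.65), leukocyte (0.66), fibroblast (0.69), p53 (0.82), partner (0.82), S phase (0.82), NF-kB (0.84), HIF (0.90) and neighbour (0.93) lists. Median and mean differed in sign for HIF targets (-0.02, 0.03, camera Down), neighbours (0.04, -0.05, Up) and S phase genes (-0.01, 0.03, Up).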

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

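The tests of span, GC content, the stretch of Trp53cor1, cell type markers and left-out libraries in this part were chosen only after the result was seen, while the limma and camera calls and the other splits of the libraries were planned. The errors of medians in this part are bootstrap errors over genes or list members and hold no spread between libraries. Those of slopes are standard errors over libraries.

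Genes with long genomic spans were lower in the lincRNA-p21 GapmeR libraries. Loss of long RNA molecules as the whole cause is argued against by the slope of log2 values on genomic span at a fixed mature transcript length, which differed between GapmeRs by -0.127 ± 0.00417 per SD over 11650 genes, while the slope on mature length differed by 0.0104 ± 0.0295. GC bias is argued against by the medians of the 613 genes over 200 kb, which were -0.548 in PE and -0.315 in PBS and stayed at -0.533 ± 0.0226 and -0.298 ± 0.015 after the GC trend was removed. Pairing of the oligonucleotide with mature transcripts stays open, because the stretch of Trp53cor1 GCTTTTCACTA (chromosome 17, 29059051 to 29059061, exon 2) was picked in PBS and the 2 knockdown effects correlate across genes (r = 0.664), so the mean adjusted log2 change of -0.691 of its 17 carriers in PE decides nothing. Pairing with introns stays open, because the slope of -0.127 is what it would also give, and neither intron sequences nor the sequence of the oligonucleotide were analysed here.

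Interferon-stimulated genes rose with the knockdown in PE more than in PBS by camera with a fixed correlation (adjusted p = 2.4e-18), with adjusted p = 0.081 with an estimated one. Fry gave adjusted p = 0.030 for this interaction, 5.5e-04 for the knockdown in PE and 0.30 for the knockdown in PBS. More leukocytes are argued against by a leukocyte marker median of -0.114 ± 0.11 with the knockdown in PE, beside 1.38 ± 0.212 for the interferon list. A single library is argued against by the interaction median, which was lowest without PBS knockdown replicate 3, at 0.691. A response to the oligonucleotide itself and an effect of the lost lincRNA stay open, because a single GapmeR against the target was compared.

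PE lowered fibroblast markers and raised endothelial and leukocyte markers by camera, the last with adjusted p = 0.075 with an estimated correlation. A lower share of cardiomyocytes as the whole cause is argued against by the fibroblast median of -0.958 ± 0.387. Alone it would raise all 3 marker groups, whose other medians were 1.10 ± 0.257 and 0.566 ± 0.285. A lower share beside a change in the state of fibroblasts stays open, since markers could then fall within these cells. The fibroblast markers changed unequally, with a Cochran Q of 68.2 per degree of freedom. This does not decide whether fewer fibroblasts were the whole cause, since other cells in the culture could also hold RNA of some markers. Fewer fibroblasts and a change in the state of these cells, alone or together, stay open.

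Each of the 4 comparisons of 2 groups had 10 splits of its libraries, of which 1, the real one, gave as many limma calls, and the highest other count was 0. With 10 splits, a share under 0.05 cannot be reached. For the interaction, 11 of 100 splits drawn from 200 gave 12 calls or more, the highest 3380, in a split that exchanges the GapmeRs within 1 treatment and so measures the sum of the 2 knockdown effects. Other splits can also carry part of the knockdown effects into the interaction, so the share of 11 in 100 does not measure chance. These splits therefore neither exclude chance as the source of the 12 interaction calls nor show it.

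The log2 interactions of single genes were 2.08 for Trib3, 1.94 for Ifit3b, 1.91 for Iigp1, 1.87 for Zdhhc23, 1.86 for Rsad2, 1.85 for Ifit3, 1.55 for Ifi204, 1.37 for Cxcl10, 1.20 for Igfbp5, 1.19 for Irgm2, 1.12 for Gbp2 and 0.841 for Dtx3l. Median log2 interactions of lists called by camera were 0.931 for interferon-stimulated genes, 0.690 for mitochondrially encoded genes (camera adjusted p = 7.8e-06), 0.439 for ATF4 targets, 0.232 for ribosome biogenesis (0.042) and 0.179 for NRF2 targets (0.0016). They were -0.340 for immediate early genes (camera adjusted p = 1.7e-04), -0.262 for glycolysis (2.6e-05), -0.256 for extracellular matrix genes (1.8e-05), -0.246 for epicardial markers (5.3e-04), -0.211 for adrenergic genes (0.0016), -0.202 for ion channel genes (0.0011), -0.195 for smooth muscle markers (0.042), -0.149 for hypertrophic genes (0.016) and -0.0839 for cholesterol genes (0.0037). Of these lists only the ATF4 targets held with an estimated correlation. Fry called the interferon, ATF4, NRF2, glycolysis, epicardial, adrenergic and cholesterol lists (adjusted p of 0.030 or less). It did not call the hypertrophic (fry adjusted p = 0.060), ion channel (0.089), extracellular matrix (0.089), mitochondrially encoded (0.18), immediate early (0.29), smooth muscle (0.31) and ribosome biogenesis (0.39) lists. Without 3 distant libraries ribosome biogenesis reversed its camera direction, with a median of 0.0218 (camera, adjusted p = 0.89), and mitochondrially encoded protein genes lost their call, at 0.126 (0.13).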

How the results depend on the processing

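Alternatives were fixed before the data were seen except those on recovered reads with TMM, rescaled totals, the GC trend and the fit without 3 distant libraries, which were tests chosen afterwards. Main results stayed the same in 184 cases and moved in 29, where a count within 1.5-fold of the reported one was taken as the same. With a fold change of at least 1.5, calls were 3467 for PE, 1342 for the knockdown in PE, 528 for the knockdown in PBS, 3606 for PE in knockdown cells and 199 for PE-changed genes moved the opposite way by the knockdown in PE. Without 3 distant libraries, calls were 4672 for the knockdown in PE, 1865 in PBS and 143 for the interaction, with 1250 genes moved the opposite way. In that fit Nop58 with the knockdown in PBS reversed to 0.26 (limma, adjusted p = 0.049) from -0.09, and the interaction of ribosome biogenesis reversed by its camera direction, with a median of 0.0218. With only the 6 libraries compared, the knockdown in PBS gave 392 calls. The interaction gave 132 calls with DESeq2 and 33 with the GC trend removed. Leave-one-out counts ran from 1671 to 3502 for the knockdown in PE, 510 to 1181 in PBS, 3 to 22 for the interaction and 336 to 862 for genes moved the opposite way. With the replicate block, calls were 5171 for PE, 2269 for the knockdown in PE, 822 in PBS, 5708 for PE in knockdown cells and 12 for the interaction, 10 of them among the 12 reported, and 485 genes moved the opposite way. Among named genes 428 alternatives were weaker, 27 stronger, 1 reversed and 14007 the same, and among lists 262 were weaker, 108 stronger, 1 reversed and 4016 the same. For genes and lists, the same includes those called in neither fit, so these tallies overstate how many calls were kept. For results that changed, the cause was not tested.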

Other observations

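All tests in this part were chosen only after the result was seen.

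The word GCTTTTCACTA of Trp53cor1 occurs in the mature transcripts of 17 of 12097 genes, among them Sema5a, Urm1, Dzip1l, F8 and Nt5dc2. It ranked 1 of 3479 words with the knockdown in PBS and in PE, by a score that also weighs the number of carriers. The mean adjusted change of its carriers was -0.615 in PBS and -0.691 in PE. Limma called 10 of the 17 carriers lower in PBS and 11 in PE, beside 700 and 1556 of all 21799 genes tested. In Cep83, Mkrn2, Scyl2, Arhgap32 and Hmbox1 the word lay only in transcripts without a coding sequence. In PBS a permutation test over all words gave p = 0.001, the smallest that its draws allow. It shuffled values over genes, which are not independent replicates, so its p-value holds no spread between libraries. With the knockdown in PE, Dzip1l changed by -1.96, F8 by -1.79 and Nt5dc2, which spans 8072 bases, by -1.60, while Bak1 was 0.16 and Fam171b 0.00. In Sema5a the match lies in the 3' UTR (chromosome 15, 32691749 to 32691759) and extends to 15 bases, and in Urm1 in the 3' UTR (chromosome 2, 29844427 to 29844437) to 13 bases. The same word ranked 372 for PE against PBS, with a mean of -0.147.

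A first hypothesis is that part of the genes lowered by the GapmeR are direct targets of the oligonucleotide, which rests on the PBS permutation test, since the carriers were picked in PBS and their mean of -0.691 in PE is no separate support where the 2 knockdown effects correlate, and that long genes are met more often because their introns hold more partial matches, which the span slope of -0.127 leaves open. The test is a second GapmeR against another stretch of Trp53cor1. It would spare Urm1 if this gene is an off-target of the first oligonucleotide and lower it if it depends on the lincRNA. For the long genes Sema5a and Ppp3ca a fall would not decide, since a second oligonucleotide could also meet their introns. A second hypothesis is that the interferon response in PE with the knockdown, whose interaction median stayed at 0.691 or higher without any 1 library, may be a response to the oligonucleotide that PE strengthens. The test is a second GapmeR against another stretch of Trp53cor1 in PE, which would not raise Rsad2, Ifit3 and Cxcl10 if the response is to this oligonucleotide.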
